A study of Apostichopus japonicus with 6 samples.

How the data were processed

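Small RNA was sequenced from intestines of the sea cucumber *Apostichopus japonicus*, a holothurian echinoderm that expels its gut (evisceration) and then regrows it. The labels give 2 groups of 3 libraries. Per the series design each library came from 3 animals, while the extraction protocol in the labels speaks of an individual intestine, so pooling is not certain. One group was sampled 3 days post evisceration (3dpe) and the other had not eviscerated (control). The libraries carry the letters A, B and C in both groups, and nothing in the labels ties a letter in 1 group to the same letter in the other.

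The authors deposited, for each library, the length and sequence of every distinct tag and the raw count of reads with exactly that sequence. Per the submitters' processing notes, CASAVA 1.5 was used. The adapter trimmer, the quality and length filters, any aligner and any genome build are not given in the sources used here. The deposited tags were 18 to 44 nt long, each sequence stood once per library, and the deposited counts were whole numbers with no normalisation. Per the labels' protocols, RNA was enriched for polyadenylated messenger RNA and fragmented before library construction, which does not describe tags of these lengths, and the small RNA library method is taken as unknown. The loss of reads in trimming and any bias of adapter ligation could therefore not be assessed.

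Depth was even, at 11749967 to 11853699 reads per library, with 749263 to 1699596 distinct tags. A count of 0 allows a level of up to 0.253 to 0.255 CPM (reads scaled to a library total of 1e6), taking 3 counts as the floor. Shares of reads in single libraries are given with 95% Wilson intervals. Reads were PCR copies without molecular identifiers, so the intervals and the floor cover counting error only.

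No genome of the species was used, so no tag has a position here. Tags were named by comparison with a list of 76 mature sequences of miRNAs written from general knowledge before the data were examined. Of these, 43 names belong to families of bilaterian animals or echinoderms, and the others, of vertebrates, protostomes or plants, served as a measure of foreign RNA. A tag of 18 to 26 nt was counted for a miRNA when it differed by at most 1 base from bases 1 to 18 of a listed sequence, at a start at most 2 nt from the listed start. The fewest differences and then the smallest shift won, and ties stayed unmatched. A sum so made can hold several members of a family, and it misses a miRNA whose sea cucumber sequence differs more from the list. On simulated tags all 380 copies with no difference and all 380 with 1 difference were matched to the right name, and 1 of 100000 random 22 nt tags was matched. The names fell into lists fixed before the data were examined, namely let-7 cluster, muscle, neural, epithelial, sensory cluster, echinoderm and other conserved. A further list of tRNA 5′ ends was written at the same time.

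Counts per miRNA were compared with edgeR 4.0.16 (quasi-likelihood F test, TMM factors over the listed miRNAs, filterByExpr) with Benjamini-Hochberg adjustment at 0.05. Single tags of 18 to 32 nt were compared by the same test when at least 3 libraries reached 5 CPM. Levels are printed as CPM of all reads of the library, and log2 fold changes come from the fit. Their standard errors were computed as the absolute log2 fold change over the square root of the F statistic. They therefore hold no information beyond the test. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, at a preset correlation of 0.01 and with an estimated one. Shares of reads were compared by two-sided exact permutation tests, for which the smallest p with 3 against 3 libraries is 0.1. The fits were made in R 4.3.3, and tags were counted with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3.

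The miRNA fit was tested on counts simulated for the 34 tested miRNAs with their own spread. It called 3 of 10 changed by 2-fold (1 of them in the wrong direction) with 1 unchanged miRNA, and 5 of 10 changed by 4-fold. For the 10226 tested tags it called 0 of 200 changed by 16-fold at the spread of the data, and 184 of 200 when every tag had the same spread, the median of tags that match listed miRNAs.

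The miRNAs named in the text were chosen before the data were examined as all those past the threshold (at most 25), all tested members of the muscle, neural, epithelial and let-7 cluster lists, and the 5 most abundant. Unmatched tags were named when they were of 20 to 24 nt, past the threshold, at a mean of at least 100 CPM and with groups that did not overlap, up to 5 in each direction by fold change. Other miRNAs and tags named were chosen after their values were seen.

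The alternatives tried were DESeq2's size factors in the same fit, scaling to all reads of the library, the Wald test of DESeq2 1.42.0, no filter on low counts, the letters as a replicate block, an exact match to the list, tags of 20 to 24 nt, a minimum of 50 CPM for tags, narrower length classes, each distinct tag counted once, other totals, and leaving out each library in turn. A robust quasi-likelihood fit, a match with up to 2 differences and a minimum of 5 CPM in 2 libraries for tags when a 3dpe library was left out were added after seeing the data. Ribosomal RNA pieces were collected by extending 9 conserved seed sequences through overlaps of 16 nt between tags into stretches of 55 to 396 nt. Pairs of tags of 26 to 32 nt whose first bases were reverse complements were counted per library over tags with at least 10 reads, with unreversed complements as background. Each pair was counted once from each of its tags. In 22000 simulated tags whose planted pairs came to 4000 when counted in this way, the count at 10 nt was 4475 against a background of 460. Energies of paired tags were computed with RNAduplex 2.7.2.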

Results

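Small RNA tags of the intestine were compared between sea cucumbers 3 days post evisceration (3dpe) and animals that had not eviscerated (control). Each group had 3 libraries, of 3 animals each per the series design, although the extraction protocol speaks of an individual intestine, so the spread between libraries is that of pools or of single animals. The libraries held 11749967, 11852458 and 11824956 reads in 3dpe A, B and C and 11813978, 11853699 and 11769727 in control A, B and C. No library repeated another of its group, since the lowest chi-square per degree of freedom over listed miRNAs was 495 between 3dpe libraries and 6929 between control libraries, which does not show whether the spread is of animals or of library preparation.

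The first comparison asked how the make-up of the small RNA differed between regenerating and intact intestine. The cell make-up of the samples was not measured. In all comparisons below, a change of level within a cell type therefore cannot be told from a change in the cells present. Reads of miRNA length, 20 to 24 nt, made up 36.7% ± 3.86 (SD, n = 3) of the 3dpe libraries and 53.3% ± 1.17 (SD, n = 3) of the control libraries. Reads of 26 to 32 nt, the length of piRNAs, which guide the silencing of transposons in animals, made up 56.3% ± 3.66 (SD, n = 3) and 42.0% ± 0.311 (SD, n = 3). Reads matched to listed miRNAs made up 25.5% ± 4.24 (SD, n = 3) of 3dpe reads and 42.6% ± 4.24 (SD, n = 3) of control reads. In each of these 3 shares the groups did not overlap, and the exact permutation p was 0.1, the smallest that 3 against 3 libraries allow, so that no share could pass a threshold of 0.05.

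At single lengths, reads of 22 nt took 17.0% ± 2.60 of 3dpe and 26.9% ± 1.92 of control libraries, and reads of 27 nt took 21% ± 2.98 and 11.6% ± 1.4 (SD, n = 3). Reads of 29 nt took 5.93% ± 0.583 and 7.41% ± 1.70. In single libraries the share of 20 to 24 nt ran from 32.7% in 3dpe C (Wilson interval 32.66 to 32.71) to 40.4% in 3dpe B (40.36 to 40.41), and from 52.2% in control C (52.19 to 52.25) to 54.5% in control B (54.52 to 54.58). Among reads of 26 to 32 nt, 80.2% ± 3.33 began with U in 3dpe and 76.0% ± 5.74 in control libraries (exact permutation p = 0.5, n = 3). Of the reads of this length that began with another base, 67.8% ± 2.73 in 3dpe and 75.9% ± 5.76 in control had adenine at base 10 (exact permutation p = 0.2), against 30.8% ± 0.662 and 32.6% ± 0.658 of those that began with U (exact permutation p = 0.1).

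**Figure D1:**
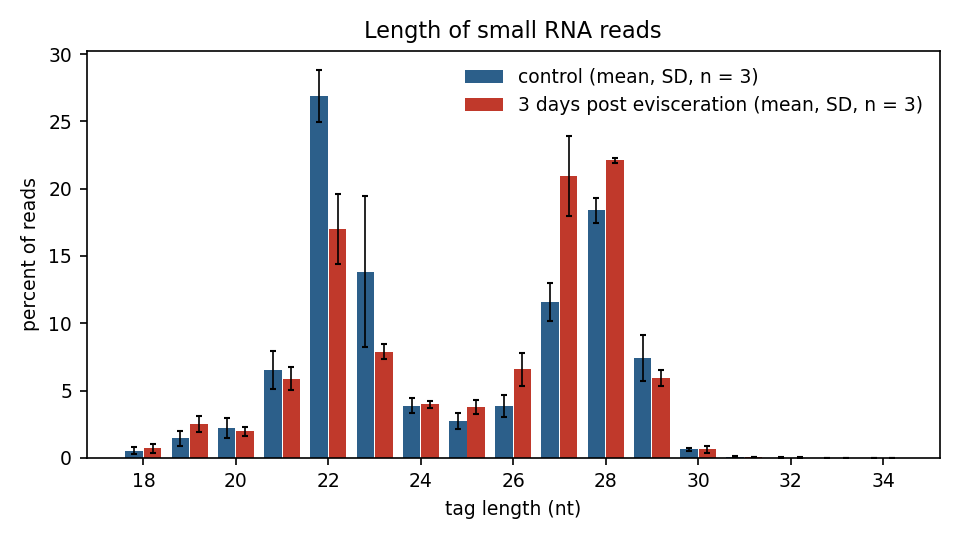
Percent of reads (y axis) at each tag length in nt (x axis), as the mean of the 3 libraries of each group with the SD as error bars. The mean of control libraries peaked at 22 nt with 26.9% and that of 3dpe libraries at 28 nt with 22.1%, and at 27 nt the means were 11.6% and 21%. In 3dpe C alone the peak was at 27 nt.

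The second comparison asked which miRNAs differed 3 days after evisceration, the question that the series title names. Of 34 listed miRNAs tested, 5 rose and 8 fell. The largest rises were those of miR-153, a miRNA of the nervous system in vertebrates, from 44.3 ± 21.8 to 701 ± 274 CPM (counts relative to all reads of the library; SD, n = 3), and of miR-252 and miR-2001, from 9.22 ± 3.91 to 90.2 ± 23.4 and from 2.39 ± 1.65 to 23.3 ± 3.65 CPM. MiR-200, a miRNA of epithelia, rose from 62.5 ± 12.1 to 239 ± 63.7 CPM. The largest falls were those of the echinoderm miR-2008, from 194 ± 282 to 6.18 ± 2.18 CPM, and of miR-375, known from endocrine cells of the gut and pancreas, from 7669 ± 10096 to 521 ± 165 CPM. Both control means were raised by control C. MiR-1, the muscle miRNA, fell from 85324 ± 21186 to 48272 ± 9256 CPM.

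By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold changes of the risen miRNAs were 3.94 ± 0.46 (SE) for miR-153 (adjusted p = 0.00217), 3.32 ± 0.54 for miR-2001 (adjusted p = 0.00879) and 3.30 ± 0.37 for miR-252 (adjusted p = 0.00217). They were 1.95 ± 0.35 for miR-200 (edgeR adjusted p = 0.0106) and 0.85 ± 0.22 for miR-2004 (edgeR adjusted p = 0.0343). Those of the fallen miRNAs were -5.05 ± 1.39 for miR-2008, -3.95 ± 1.1 for miR-375, -1.47 ± 0.36 for miR-210, which hypoxia induces in vertebrates, and -1.46 ± 0.35 for miR-2011, all at an edgeR adjusted p of 0.0343. MiR-2013 fell by 0.84 (SE 0.22), miR-1 by 0.84 (SE 0.26), miR-71 by 0.81 (SE 0.22) and miR-2002 by 0.73 (SE 0.22) on the log2 scale, at edgeR adjusted p of 0.0343 to 0.0449. All 13 had groups that did not overlap when scaled by the TMM factors of the fit, which their choice by the test nearly ensures. In CPM of all reads miR-2002 did overlap, at 12452 in 3dpe B and 12208 in control A. At an unadjusted p under 0.05, 20 miRNAs stood. Scaled to all reads of the library, the calls of miR-1 (-0.82 ± 0.27), miR-2013 (-0.84 ± 0.28), miR-2002 (-0.73 ± 0.27) and miR-2004 (0.86 ± 0.28) ended, at edgeR adjusted p of 0.0599 to 0.0717, with log2 fold changes nearly unchanged and larger SE for these 4. DESeq2's size factors in the same fit called 8 higher and 7 lower, against 5 and 8, and shifted the median log2 fold change of all miRNAs by 0.13. With no filter the calls were 8 higher and 4 lower with a shift of 0.32, and with up to 2 differences 9 higher and 4 lower with a shift of 0.34, so neither changes of up to that size nor the balance of rises and falls has a settled direction.

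Of the 5 most abundant listed miRNAs, miR-1 and miR-71 fell and miR-10, let-7 and miR-2012 did not pass. MiR-10, encoded in Hox clusters, made up 143220 ± 93102 CPM in control and 58195 ± 10557 CPM in 3dpe libraries (log2 fold change -1.27 ± 0.57, edgeR adjusted p = 0.107). Its level in control C was below that in the other controls, and without control C its log2 fold change was -1.55 with an edgeR adjusted p of 4e-04. MiR-2012 had a log2 fold change of 0.50 ± 0.20 (edgeR adjusted p = 0.0801).

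In the echinoderm list, 1 of 9 tested members rose (miR-2004), 4 fell (miR-2008, miR-2011, miR-2013 and miR-2002) and 4 did not pass. The counts adjusted over the list alone were also 1 and 4. The balance was not settled, since without control C, and also with up to 2 differences from the list, miR-2004, miR-2010 and miR-2012 rose and only miR-2008 and miR-2011 fell. In the epithelial list, miR-200 rose and miR-375 fell, and miR-7 (0.71 ± 0.28, edgeR adjusted p = 0.0801) and miR-31 (0.20 ± 0.20, edgeR adjusted p = 0.471) did not pass, with 1 and 1 again when adjusted over the list alone. In the neural list, miR-153 alone rose of 5 tested, also when adjusted over the list alone. Its other members had log2 fold changes of -0.37 ± 0.27 (miR-124), -0.19 ± 0.31 (miR-137), -0.01 ± 0.50 (miR-79, positive with DESeq2's size factors and relative to all reads) and 0.27 ± 0.34 (miR-9). Reads per library were few for miR-79 (9 to 20), miR-9 (42 to 76) and miR-137 (102 to 169), against 4388 to 8413 for miR-124. In the muscle list, miR-1 fell and miR-133, at 14.1 ± 3.55 CPM in 3dpe and 15.1 ± 7.33 CPM in control, had a log2 fold change of -0.10 ± 0.45 that was positive with DESeq2's size factors. Adjusted over the list alone, miR-1 was again the 1 lower member.

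Neither tested member of the let-7 cluster passed, over all miRNAs or adjusted over the list alone. Let-7 had a log2 fold change of -0.38 ± 0.26 (edgeR adjusted p = 0.276) and miR-125 of 0.06 ± 0.20 (edgeR adjusted p = 0.825), and by edgeR's unadjusted p neither was under 0.05 either. Of the other conserved miRNAs, 11 were tested, miR-252 and miR-2001 rose and miR-210 and miR-71 fell, and adjusted over the list alone 2 were higher and 3 lower. The third lower one was miR-34, from only 84 to 411 reads per library. A match with up to 2 differences gave it 50069 to 213971 reads, and it did not pass (edgeR adjusted p = 0.106). The sensory cluster had 1 tested member, miR-96, which did not pass over all miRNAs (edgeR adjusted p = 0.0801) and counted as 1 higher when adjusted over the list alone. MiR-96 had 1157 reads in 3dpe C and 8 to 28 in each of the other libraries.

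No list passed as a set by camera (adjusted p from 0.786 to 0.813 at the preset correlation, and 0.869 with an estimated correlation), so there were no calls to be lost with an estimated correlation. The single tested member of the sensory cluster made no set. The median, mean and test differed in sign in 3 lists, the epithelial (median 0.45, mean -0.27, test up), the neural (median -0.01, mean 0.73, test up) and the other conserved list (median -0.59, mean 0.07, test down).

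Leaving out 3dpe A, B or C left 4, 4 and 5 called miRNAs, which were miR-153, miR-2001, miR-252 and miR-200, with miR-2004 as the fifth without 3dpe C. The 8 falls kept their direction there but not their calls (edgeR adjusted p 0.0942 to 0.286), at log2 fold changes of -5.19 to -4.61 for miR-2008, -4.02 to -3.44 for miR-375 and -1.51 to -0.46 for the others, smallest without 3dpe C. Leaving out a control library ended the calls of miR-1 and miR-71 (control A), miR-2002 and miR-2004 (control B) or miR-2002 and miR-2013 (control C). Without control C the log2 fold change was -2.16 for miR-2008, -1.64 for miR-375, -0.82 for miR-210 and 4.62 for miR-153, and without control B that of miR-2001 was 3.92, all still called.

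**Figure D2:**
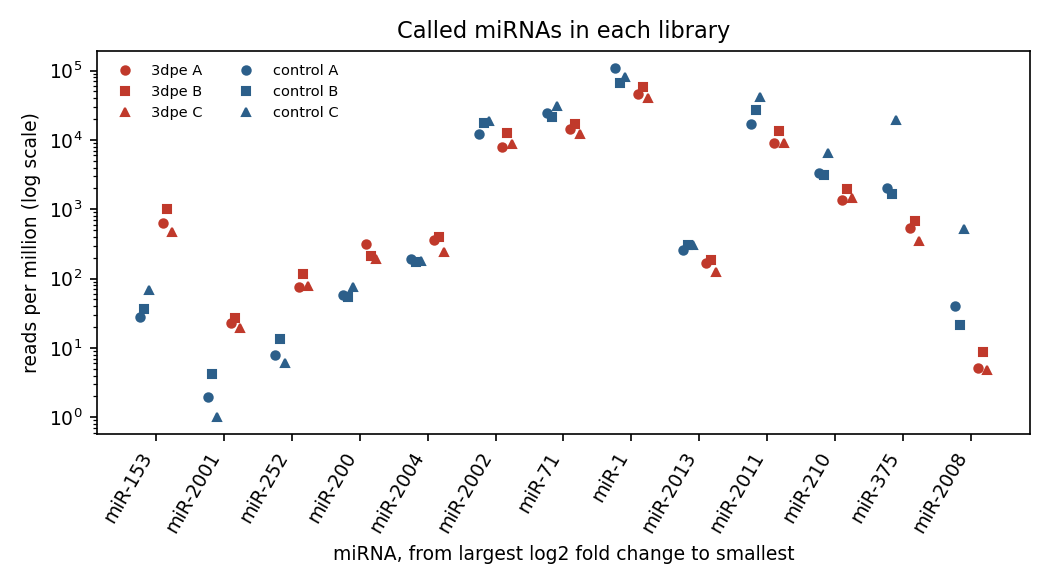
CPM (y axis, log scale) of the 13 called miRNAs (x axis, in order of log2 fold change) in each of the 6 libraries, with a point per library and no error bars. Control C stands above the other control libraries for miR-375 and miR-2008, and miR-153 has a mean of 701 CPM in 3dpe and 44.3 CPM in control libraries.

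The third comparison took every tag on its own, with no list of names. Of 10226 tags of 18 to 32 nt, 162 rose and 47 fell by edgeR's quasi-likelihood test. Of 6387 unmatched tags of 26 to 32 nt, 110 rose and 43 fell. Of 2262 unmatched tags of 20 to 24 nt, 32 rose and 2 fell, while the median log2 fold change of all of them was -0.44. That median depended on the scaling. When all 2755 tags of 20 to 24 nt, matched ones among them, were fitted alone, their log2 fold changes shifted by a median of 0.45. Their median was then -0.05, with TMM factors taken over these tags only. The fit of these tags alone also called more of them, 171 higher and 27 lower. Of 550 tags matched to listed miRNAs, 3 rose and 2 fell. The 5 largest rises among abundant unmatched tags of miRNA length belonged to 2 sequence families, and 0 fallen tags met the same rule by edgeR.

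The tag AGAATAATGGATTAGATGAAA rose from 0.621 ± 0.275 to 234 ± 119 CPM (SD, n = 3), a log2 fold change of 8.28 ± 0.70 (edgeR adjusted p = 0.0266). Its longer forms AGAATAATGGATTAGATGAAAAA and AGAATAATGGATTAGATGAAAAAA rose by 8.64 ± 1.32 (edgeR adjusted p = 0.0445) and 8.78 ± 1.31 (edgeR adjusted p = 0.0433) on the log2 scale. The tag AACAGGATTAGGAGTAGGATGGC rose from 0.367 ± 0.177 to 256 ± 173 CPM, a log2 fold change of 9.10 ± 0.89 (edgeR adjusted p = 0.0335), and AACAGGATTAGGAGTAGGATGGCC by 8.54 ± 1.18 (edgeR adjusted p = 0.0390). Tags of 26 to 32 nt that begin with the same AACAGGATTA were together at 8557 ± 1570 CPM in 3dpe and 6462 ± 1746 CPM in control libraries (exact permutation p = 0.3, n = 3), and all 18 abundant ones fell below 1% of their highest level in some library. With no genome, the loci of both families are not known here, nor whether the tags that begin AGAATAATGGATTAGATG are of the sea cucumber or of another organism in its gut.

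Of all tested tags, 3347 (32.7%) had groups that did not overlap on the scale of the fit, and 1974 stood at an unadjusted p under 0.05. Chance gives 10% for a single tag, but tags of the same libraries are not independent, so the excess was not tested. Among tags matched to listed miRNAs the share without overlap was 53.6%, and among unmatched tags of 26 to 32 nt it was 27%. Leaving out any of 3dpe A, 3dpe B, 3dpe C, control A, control B or control C left 0 called tags by edgeR, with 686 to 2063 at an unadjusted p under 0.05, and DESeq2's Wald test on all libraries called 1269 higher and 1060 lower. Without a 3dpe library, tags found only in that group missed the minimum of 3 libraries, but a minimum of 2 libraries, chosen after seeing the data, also left 0 (1678 to 2851 at an unadjusted p under 0.05), while in the fits that tested the named tags their log2 fold changes were 7.28 to 9.85, none past the threshold.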

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

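The tests of explanations here were chosen after the results they bear on had been seen, and those of sequencing errors and of sequence variants were specified before their own values were computed. The test of the label of control C replaced several earlier ones, of which the last, a count of called miRNAs nearer to the other controls (10 of 14, leaving out miR-375, miR-2008 and miR-10) and a stricter bound on the share outside the interval, had left it open. The test that replaced them leaves it open too, while the shares of reads by length and the number of distinct tags argue against a swap.

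Reads matched to listed plant miRNAs, which lie outside the comparisons, reached 44 in 3dpe C against at most 10 in a control library, with 5 as the median of the 3dpe libraries. Reads over 32 nt, also outside them, reached 1548 in 3dpe C against at most 1476 in a control library.

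More distinct tags were present 3 days after evisceration, 1393617 ± 290101 (SD, n = 3) against 803341 ± 46853, at nearly equal numbers of reads. When every library was thinned to 4900000 reads of 26 to 32 nt, the ratio of distinct tags of this length was still 1.47 with the groups apart, which argues against the smaller share of miRNA reads as the whole cause. Degraded longer RNA as the whole cause is argued against by the share of distinct tags that began with U, 77.6% ± 2.06 in 3dpe and 73.7% ± 4.40 in control libraries (3.88 points higher, groups overlapping), where fragments would lower it, but reads at the 28S ribosomal RNA end (1.5% against 0.608%) and tRNA 5′ ends (317 against 104 CPM) were higher in 3dpe libraries, so a part stays open. Reads with 1 difference from the 5 most abundant miRNA tags were 1.19 ± 0.0762 (SE) times as frequent as in control, too near the bound set for them of 1.2, so more sequencing errors may account for part of the pattern. An effect of evisceration itself on the variety of these tags stays open and was not tested apart from these.

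Control C stood apart from control A and control B. It had 11.2 times their mean of miR-375 and 17.4 times their mean of miR-2008, and they had 4.67 times its level of miR-10. Whether control C is a library of the other group stays open. Of 34 tested miRNAs, 18 (9 relative to all reads) lay outside the 95% prediction interval of the 3dpe libraries. MiR-375, miR-2008, miR-153, miR-252 and miR-2001 were in both counts. Such a count cannot decide the label, since an atypical library of either group would also lie outside. The miRNAs of a library also share a scale factor, so the 5% expected of independent miRNAs is no fair yardstick. Of 14 miRNAs called without control C, leaving out miR-375, miR-2008 and miR-10, 10 lay nearer to the other controls, among them miR-153, miR-252 and miR-2001. The other 4 (miR-2010, miR-2012, miR-29 and miR-33), miR-10 and tags beginning AAAAGGATTT (4326 CPM against 3843 ± 555, SD, n = 3) lay nearer to the 3dpe mean. A greater share of epithelium could raise miR-375, but the other 3 tested epithelial miRNAs were higher in control C by a median of only 0.35 on the log2 scale. Differences between the pools of animals or in the part of the intestine sampled stay open as untested, and the design names no biological explanation for a single library.

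Abundant tags of 26 to 32 nt were nearly missing from some libraries. Of 306 unmatched tags with at least 5000 reads in a library, 203 fell below 1% of their highest level in another. The pattern was not limited to this length, since 28 of 42 unmatched tags of 20 to 24 nt did so. Of these 28, 10 were low in exactly 3 libraries, and 5 of the 10 were low in a whole group and in no library of the other. A library-wide fault is argued against by the listed miRNAs, of whose 62 equally abundant tags 0 did so. Evisceration as the main cause is argued against because 12 of the 203 tags (5.91%) were low in a whole group and in no library of the other. Of the 45 tags low in exactly 3 libraries, however, these 12 made up 26.7%, where chance gives 10% for a single tag and the tags are not independent. Sequence variants between the pools stay open. Of the 203 tags, 26.6% had a tag of equal length with 1 difference at no less than 10% of their highest level in a library that lacked them. How often other abundant tags have such a neighbour was not measured, so this share cannot decide for or against variants.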

How the results depend on the processing

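The robust fit, the match with up to 2 differences, the minimum of 2 libraries and the test by splits of the libraries were specified after seeing the data. The 3 shares of reads kept direction under every alternative run, while their exact permutation p, never under 0.1, could not change side of the threshold. The 6 tested lists kept direction and stayed short of it. The difference in the share of 20 to 24 nt ran from -18.5 to -2.44 percentage points, that of 26 to 32 nt from 2.49 to 15.7 and that of reads matched to listed miRNAs from -19.4 to -10.5, with the ends nearest 0 of the first pair from counting each distinct tag once. Adjusted p of the lists ran from 0.711 to 0.948.

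Against 13 called miRNAs (5 higher, 8 lower), the exact match called 5 (28 tested, 4 higher and 1 lower) and the replicate block 4 (4 higher and 0 lower). Leaving out a library gave 4 to 17, of which the 17 without control C held 11 of the 13. The other 7 alternatives called 9 to 17. MiR-153, miR-252 and miR-200 kept their calls in all 15 alternatives and miR-2001 in the 14 that tested it. Against 209 called tags, DESeq2's Wald test called 2329 (208 of the 209 among them), no filter 2781 (of 4661967 tags, 99 of the 209 among them), 50 CPM 81 (of 992, fewer being tested, 39 of the 209 among them) and the replicate block 0 by edgeR, with 1492 at an unadjusted p under 0.05. Leaving out a library gave 0 in each case by edgeR, with 686 to 2063 at an unadjusted p under 0.05, and without a 3dpe library and with 5 CPM in 2 libraries also 0, with 1678 to 2851. Tags of 20 to 24 nt alone gave 171 higher and 27 lower, of which 38 were called before. Beyond fewer libraries or tags tested, the cause was not tested. Scaling to all reads moved the median log2 fold change of tags by 0.26.

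No pairing of the libraries by letter was seen, but 3 libraries per group cannot exclude one. Correlations of deviations between libraries of equal letter were 0.06, -0.04 and -0.21 over miRNAs and -0.01, 0.07 and 0.02 over tags. Between other letters they ran from -0.45 to 0.32 over miRNAs and from -0.12 to 0.11 over tags. Not every library correlated best with its own letter.

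Only named miRNAs that did not pass changed sign. Over the fits without a library, let-7 ran from -0.51 to 0.079, miR-125 from -0.0044 to 0.36, miR-137 from -0.29 to 0.10, miR-133 from -0.26 to 0.40 and miR-79 from -0.30 to 0.50. MiR-133 was at 0.034 with DESeq2's size factors and its Wald test, 0.20 with no filter, 0.0048 with the replicate block, 0.078 with an exact match and 0.22 with 2 differences. MiR-79 was at 0.14 with DESeq2's size factors and its Wald test, 7.5e-05 relative to all reads, 0.31 with no filter, 0.044 with the replicate block and 0.33 with 2 differences. MiR-137 was at 0.11 with no filter, 0.0094 with an exact match and 0.12 with 2 differences. In the remaining miRNA values 258 kept their side of the threshold, 62 lost a call and 11 gained one, the gains being those of miR-7, miR-2012 and miR-10. Of the values of named tags, 33 kept their call and 37 lost it. Without a 3dpe library the named tags did not reach 5 CPM in 3 libraries, and with a minimum of 2 libraries their adjusted p was 0.0818 to 0.210.

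Of the 10 splits of the 6 libraries into groups of 3, only the real split (1 of 10) called any miRNA or tag. It called 13 miRNAs and 209 tags, the highest of the others was 0 of each, and 10 splits are too few for a share under 0.05. At this depth a tag with a count of 0 may still have a level of up to 0.253 to 0.255 CPM, taking 3 counts as the floor.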

Other observations

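All measures in this part were chosen after seeing the data. A table of 32 of them was compared between the groups, of which 16 had groups that did not overlap. Many of them count the same reads, and all were chosen late, so no chance rate applies. With an exact permutation p of at least 0.1 each, the lowest p adjusted over them was 0.2, so none passed. The lengths of single miRNAs, the pairs at 13 nt, the fit of miR-34 and the pairing energies stand outside this count.

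Products of reciprocal cleavage by PIWI proteins pair over their first 10 nt. Pairs of tags of 26 to 32 nt at 10 nt outnumbered unreversed ones by 24.9 ± 3.73 times (SD, n = 3) in 3dpe and 49.7 ± 13.1 times in control libraries, against 3.25 ± 0.194 and 4.38 ± 0.580 times at 9 nt and 8.56 ± 1.04 and 18.3 ± 5.77 times at 11 nt. The lower ratio in 3dpe came with more unreversed pairs, 2106 to 2710 against 856 to 1024, and not with fewer pairs, 52988 to 61093 against 42545 to 55482. Both counts grow with the number of tags entered, and 3dpe libraries held more distinct tags of 26 to 32 nt, 979704 ± 204418 against 544568 ± 27153. Whether pairing per tag differed cannot be read from these counts. At 13 nt the ratio was 28.1 to 512.5 in single libraries, but over a background of only 4 to 88 unreversed pairs, so it cannot be set against that at 10 nt. Pairs numbered 14976 to 35782 at 9 nt, 42545 to 61093 at 10 nt, 3562 to 6402 at 11 nt and 2050 to 3248 at 13 nt. Over distinct starts the ratio at 10 nt was 5.72 ± 0.152 and 7.63 ± 0.303. Reads with such a partner made up 36.6% ± 6.98 of 3dpe and 45.4% ± 2.10 of control reads of this length in tags with at least 10 reads, with a background of 1.63% ± 0.318 and 1.03% ± 0.259. Without 6 tag families the shares were 31.0% ± 6.69 and 38.4% ± 2.78, with overlapping groups (exact permutation p = 0.2). Tags beginning AAAAGGATTA and their partners beginning TAATCCTTTT were among the largest such families, at 14416 ± 2266 and 7813 ± 753 CPM in 3dpe and 22252 ± 6450 and 7660 ± 1420 CPM in control libraries. All 40 abundant tags of the first family fell below 1% of their highest level in some library, while the sum of the family differed at most 2.19-fold between libraries. Tags beginning AAAAGGATTT were at 3843 ± 555 CPM in 3dpe libraries and at 41.5, 15 and 4326 CPM in control A, B and C, so that control C lay with the 3dpe libraries.

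Reads beginning at the tag CCAGACCTCAGATCGGATG, which tag overlaps extended into the 5′ end of 28S ribosomal RNA, made up 1.5% ± 0.398 (SD, n = 3) of 3dpe and 0.608% ± 0.264 of control reads, while the other ribosomal pieces made up 2.48% ± 0.585 and 2.51% ± 1.13. Reads matched to listed tRNA 5′ ends were at 317 ± 58.8 CPM in 3dpe and 104 ± 24.2 CPM in control libraries. Let-7 was more often 21 nt long in 3dpe libraries, in 21.6% ± 1.49 of its reads of 21 and 22 nt against 15% ± 0.628. Of 28 miRNAs with at least 50 reads in every library, 8 had a shorter mean length in 3dpe without overlap of the groups and 3 a longer one (39.3% together). These lengths came from the same libraries and were chosen late, so no chance rate applies to them either.

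The family that begins AGAATAATGGATTAGATG had 72634, 12160 and 9326 reads in 3dpe A, B and C and 82, 63 and 54 in control A, B and C. After base 18, or after a G at base 19, 91.6% ± 7.58 of its reads in 3dpe held adenine alone. The share in control libraries was 83.1% ± 3.84, with overlapping groups (exact permutation p = 0.3). MiR-34 was found mainly with up to 2 differences from the list, led by CGGCAGTGTGGTAAGCTGGTT, with 56077, 70122 and 50069 reads in 3dpe A, B and C and 73440, 116453 and 213971 in control A, B and C (log2 fold change -0.84 ± 0.36, edgeR adjusted p = 0.106). Listed vertebrate miRNAs had at most 15 reads in a library and listed protostome miRNAs at most 2.

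The tag CGTATTAACAATGGGGCTGATG and its variants fell with miR-2008, from 497 ± 735 to 15.1 ± 6.48 CPM (SD, n = 3), and had 1346 CPM in control C. A candidate explanation is that it is the other arm of the miR-2008 hairpin. RNAduplex gave -23.8 kcal/mol for its pairing with miR-2008, and 0 of 891 other abundant unmatched tags of 20 to 24 nt paired as well with miR-2008, the next at -18.8 kcal/mol. The hairpin itself was not seen, since no genome was used here.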
